A study of Mus musculus with 8 samples.

How the data were processed

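RNA of mouse embryonic stem cells in primitive endoderm medium was measured in 8 libraries of 4 groups, Mettl3 WT, Mettl3 cKO, Virma WT and Virma cKO, with 2 libraries each, grouped by the titles in the labels. Per the labels' protocols, RNA was extracted with TRIzol, total RNA libraries were made with a SMARTer stranded kit and a VAHTS universal kit, and sequencing was on an Illumina instrument; which library was made with which kit is not given in the sources used here. The deposited table holds raw counts per gene symbol, 21812 symbols of which 3527 have no count in any library. Per the submitters' processing notes the tools were FastQC 0.12.1, Trim Galore, STAR 2.7.11b, Subread and DESeq2, with the build mm39; their roles, the gene annotation, the strand setting and the treatment of reads with several positions are not given in the sources used here. Genes with near-identical copies, such as histone, ribosomal protein and Zscan4 genes, and antisense pairs are therefore uncertain. RNA stability, which the series also names, is not analysed here.

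Before any test the libraries of each group were compared with the sampling noise of their counts by a chi-square test over genes with a pair sum of at least 10. Over all genes together the Virma cKO pair differed by less than sampling noise and entered as 1 sample, its rounded mean, although it differed by more in the 505 genes with a pair sum of at least 10000 (chi-square per degree of freedom 3.46). This departs from the fit fixed at the start, which took all 8 libraries separately; those counts stand beside the main ones. The lone sample is assumed to vary like the other groups, and 3 residual degrees of freedom remain. The test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, robust dispersion and the filter filterByExpr over the 4 groups, which kept 14229 genes, and Benjamini-Hochberg adjustment with a threshold of 0.05. Contrasts were cKO against WT within each line, the difference of the 2 effects, and WT against WT. Overlaps of calls were tested with Fisher's exact test, two-sided. Normalised CPM were computed from the counts with the TMM factors of the 8 libraries.

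Gene lists and the naming rule were fixed before the data were examined. So were the tests and the alternatives, except the main fit and the other settings named below as chosen after the data were seen. There were 26 lists, of which 25 had at least 5 tested members; the sex-linked list had 4 and no list test. They were tested with camera of limma 3.58.1 with a preset correlation of 0.01, two-sided, and also with an estimated correlation and with fry. Fry tests whether the genes of a list move one way and compares them with no other genes. With an estimated correlation camera also uses only the 3 residual degrees of freedom, so a larger p need not reflect correlation among members. In Mettl3 cKO the estimate was −0.067 for primitive endoderm transcription factors, below the preset, and 0.051 for cholesterol synthesis, above it. Both lists lost their call. The naming rule takes Mettl3 and Virma, the 8 largest rises and 8 largest falls per knockout comparison among called genes with an average log2 CPM of at least 2 and groups that do not overlap, all tested primitive endoderm transcription factors and m6A writers, up to 4 members of each other list, the 6 genes per direction changed in both lines, and the 6 per direction whose effects differ. It leaves out predicted genes, pseudogenes and clone names, and 101 of the genes it names, from which the text takes its examples, were carried through the alternatives that give values per gene, except mt-Nd3 and Rpl10l where mitochondrial and ribosomal protein genes were removed, and with the Virma WT control for Mettl3 cKO alone. Some of the other genes it names are not reported here.

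Alternatives were DESeq2 1.42.0, its size factors in edgeR, scaling by total count, no filter or a CPM of at least 1 in all libraries of a group, an adjusted p of 0.01, a 2-fold minimum, each line on its own, the replicate number as a block, removal of mitochondrial, ribosomal protein and histone genes, removal of a loess trend with gene length and GC content, and leaving out each library. Chosen after the data were seen were the main fit with the Virma cKO pair as 1 sample, which made the planned fit of 8 separate libraries an alternative, both Virma pairs as 1 sample each, and the Virma WT libraries as control for Mettl3 cKO. Gene length, GC content and exons came from GENCODE M21 on GRCm38, another build than the authors'; 21154 symbols matched directly and 25 through older names, 633 did not, and no coordinates are used. On simulated counts 50 genes were changed per fold size among 14229, drawn only from genes at a mean of 2 CPM or more. The Mettl3 comparison recovered 74, 82, 94 and 100% at 1.3, 1.5, 2 and 4-fold, with 4.89% of calls false. The Virma comparison recovered 52, 70, 86 and 100%, with 5.52% false. Few genes were changed there, and each gene had the same spread in all groups. In the data 55.06 and 52.28% of genes were called and the pairs differed in noise, so these rates need not hold. At 15568628 to 17306227 counts per library, genes with few counts have a wide counting error, and intervals cover that error only.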

Results

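Total RNA of mouse embryonic stem cells kept in a medium that induces primitive endoderm, the extraembryonic endoderm of the blastocyst, was sequenced in 8 libraries. They belong to 2 lines, named after Mettl3 and Virma, which encode the catalytic and a scaffold subunit of the complex that writes N6-methyladenosine (m6A) on RNA. Each line has 2 libraries labelled WT and 2 labelled cKO. Total counts were 17082726 and 17107106 in Mettl3 WT, 16683597 and 16617596 in Mettl3 cKO, 17306227 and 17235657 in Virma WT, and 15630124 and 15568628 in Virma cKO. Over 14680 genes together the Virma cKO libraries differed from each other by less than the sampling noise of their counts (chi-square per degree of freedom 0.914) and were counted as 1 sample, so values of that group have no SD. The value for the Mettl3 WT pair was 2.84, for Mettl3 cKO 1.62 and for Virma WT 1.31. This varied with depth: in genes with a pair sum of at least 10000 the Virma cKO pair differed by more than sampling noise (3.46), and in genes with a pair sum under 500 the Virma WT pair, kept as 2 samples, differed by less (0.778 under 100 and 0.836 from 100). Mettl3 WT libraries also had the fewest genes with a count, 15452 and 15415, against 16476 to 17086 in the others. The labels name no separate cultures, so the p-values measure the spread between libraries, which may be technical. Values below are log2 fold changes ± SE, or normalised CPM (counts scaled to library size) ± SD with n = 2.

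The targeted genes were examined first. Mettl3 stood at 35.5 ± 0.371 CPM in Mettl3 WT and 34.6 ± 1.05 CPM in the libraries labelled Mettl3 cKO, a log2 fold change of −0.04 ± 0.07 that did not pass the test (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.695). Measured against the Virma WT libraries, a control added after the data were seen, Mettl3 was lower there by a log2 fold change of −0.38 (edgeR, adjusted p = 4.41e-05). However, Mettl3 was also higher in Virma WT (45.0 ± 1.11 CPM) than in Mettl3 WT, by 0.34 ± 0.07. The value of −0.38 therefore cannot be read as loss of Mettl3. Virma fell by 0.33 ± 0.06 in the libraries labelled Virma cKO, from 91.0 ± 3.24 to 72.3 CPM, and Mettl3 fell there by 0.42 ± 0.09. In the libraries labelled Mettl3 cKO, Virma had a log2 fold change of 0.08 ± 0.05 (edgeR, Benjamini-Hochberg adjusted p = 0.148), which passed without replicate 2 of Mettl3 WT (0.14, adjusted p = 0.0203), with the trend with gene length and GC content removed (0.28, adjusted p = 2.24e-05) and against Virma WT (0.22, adjusted p = 0.000391). Counts per gene do not show which exons are lost, and the labels are therefore not checked by these values. Directions in the knockout comparisons are between libraries labelled cKO and WT.

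The first comparison asks how the libraries labelled Mettl3 cKO differ from those labelled Mettl3 WT. Transcription factors of the primitive endoderm were lower: Gata6, a master regulator of this lineage, fell from 153 ± 8.61 to 93.2 ± 3.82 CPM (−0.72 ± 0.05). Klf6 (−0.79 ± 0.04), Sox7 (−0.54 ± 0.05), Foxq1 (−0.39 ± 0.05) and Gata4 (−0.29 ± 0.03) also fell, while Sox17 stood at −0.04 ± 0.08 and Hnf4a at −0.16 ± 0.22 without passing the test. Of the effectors of this lineage, the water channel Aqp8 fell by 1.45 ± 0.05, the laminin chains Lama1, Lamb1 and Lamc1 fell by 0.77 ± 0.02, 0.68 ± 0.02 and 0.68 ± 0.02, and the endocytic receptor Cubn fell by 0.70 ± 0.03. Foxa2 fell by 0.30 ± 0.10 with edgeR (Benjamini-Hochberg adjusted p = 0.0115), a call lost without replicate 1 of Mettl3 cKO (−0.22, adjusted p = 0.144) and with DESeq2 (adjusted p = 0.102).

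In all, 7 of 9 transcription factors fell and 0 rose, with a median log2 fold change of −0.33 (camera, Benjamini-Hochberg adjusted p = 0.000169; adjusted p = 0.131 with an estimated correlation). Among the effectors 14 of 19 fell and 2 rose, with a median of −0.54 (camera, adjusted p = 4.26e-26; adjusted p = 0.0591 with an estimated correlation). Adjusted over the list alone, 7 transcription factors and 15 effectors fell. Beside these lists, fibroblast markers rose in 12 of 13 members, median 1.05 (camera, adjusted p = 5.74e-07; adjusted p = 0.131 with an estimated correlation), and 12 also when adjusted over the list alone. Col1a1 rose by 1.12 ± 0.05 and Col3a1 by 1.15 ± 0.06, and the summed level of the list was 205.6 ± 5.87 CPM in Mettl3 WT and 386.6 ± 4.03 CPM in Mettl3 cKO. Against the Virma WT libraries 6 of 9 transcription factors were lower and 1 higher, with a median of −0.39 (camera, Benjamini-Hochberg adjusted p = 0.046, or 0.347 with an estimated correlation). Their mean shrank from −0.395 to −0.268. Of the effectors 13 of 19 were lower and 3 higher, with a median of −0.33 (camera, adjusted p = 1.39e-07, or 0.177 with an estimated correlation). The fibroblast list turned to −0.50, Col1a1 to −0.39, Col3a1 to −0.60 and Foxa2 to 0.05. Against that control Gata6 was lower by a log2 fold change of −0.22 and Aqp8 by −0.59, and Sox17 was higher by 0.23 (edgeR, Benjamini-Hochberg adjusted p = 0.0123).

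**Figure D1:**
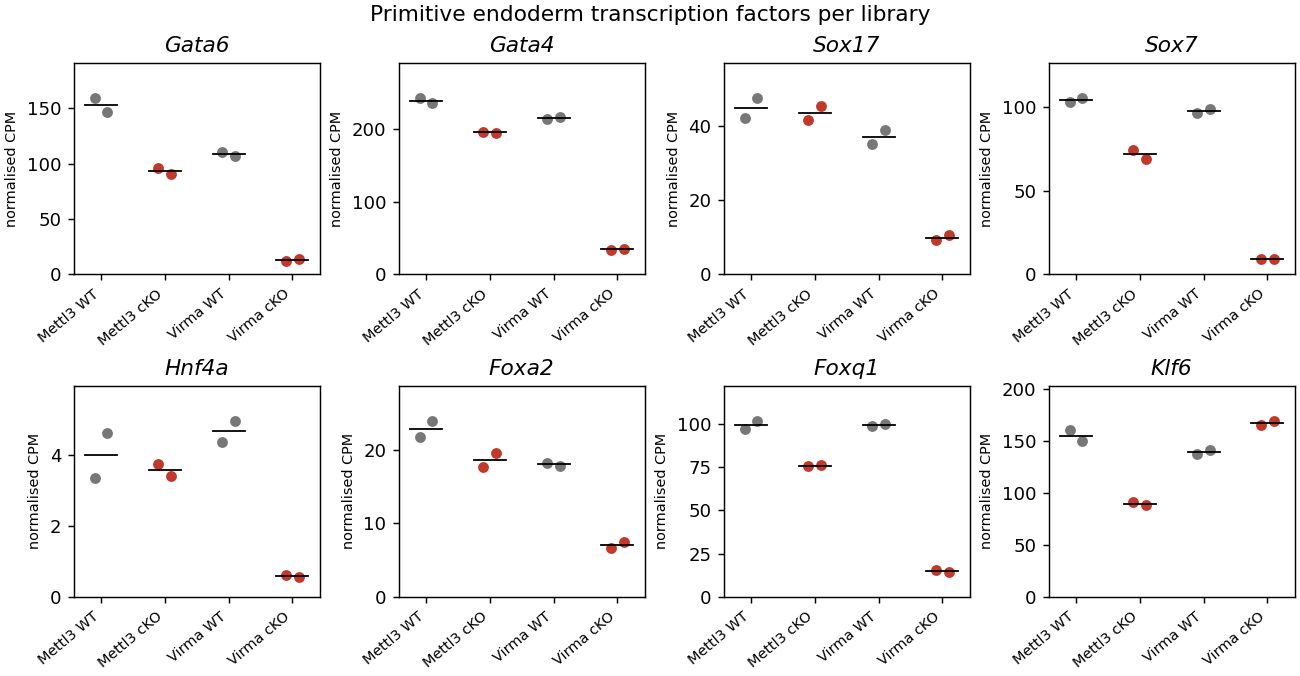
Normalised CPM (vertical axes, starting at 0) of 8 primitive endoderm transcription factors in each library of the 4 groups. Points are libraries, grey for WT and red for cKO, and black lines are group means. Gata6 stood at 153 CPM in Mettl3 WT, 93.2 in Mettl3 cKO, 109 in Virma WT and 12.9 in Virma cKO.

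Pluripotency genes of the same libraries went both ways. Pou5f1, a core pluripotency factor, rose by 0.31 ± 0.03, whereas Nanog fell by 0.23 ± 0.04, Klf5 by 0.85 ± 0.04, Tet2 by 0.85 ± 0.05 and Dppa5a by 0.60 ± 0.03. The list had 7 members up and 8 down of 20, and was not called (camera, Benjamini-Hochberg adjusted p = 0.131). Once the trend with gene length and GC content was removed, camera called the list lower (median −0.08, adjusted p = 0.0111; 0.00816 with the replicate block), and the rise of Pou5f1 did not pass the edgeR test (0.04, Benjamini-Hochberg adjusted p = 0.194). Among formative and primed epiblast genes 7 of 14 rose and 6 fell (adjusted p = 0.67 with camera), with Utf1 up by 0.96 ± 0.05, Tcf15 up by 0.90 ± 0.05, and the DNA methyltransferase genes Dnmt3b and Dnmt3l lower by a log2 fold change of −0.33 ± 0.04 and −0.46 ± 0.04. The median of this list turned from 0.53 to −0.45 against the Virma WT libraries, where camera called it lower (Benjamini-Hochberg adjusted p = 0.00743; adjusted p = 0.295 with an estimated correlation).

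Metabolic and growth genes were mostly lower. In cholesterol synthesis 14 of 16 genes fell and 0 rose, including Insig1 (−0.75 ± 0.05), and in glycolysis 12 of 16 fell and 3 rose, with Ldha at −0.48 ± 0.03. Camera called both (Benjamini-Hochberg adjusted p = 1.80e-06 and 7.87e-06), and adjusted p = 0.131 and adjusted p = 0.16 with an estimated correlation. Cell cycle genes fell in 13 of 20 and rose in 3 (camera adjusted p = 0.00551; adjusted p = 0.185 with an estimated correlation); Ccnd1, a cyclin of the G1 phase, rose by 1.14 ± 0.08, and the inhibitor Cdkn1b fell by 1.17 ± 0.09. Imprinted genes fell in 8 of 13 and rose in 3 (camera adjusted p = 6.57e-06; adjusted p = 0.131 with an estimated correlation), led by Igf2 (−1.95 ± 0.10) and Peg10 (−1.37 ± 0.03). Counts adjusted over the list alone were equal in these 4 lists. Against the Virma WT libraries camera no longer called cholesterol synthesis (4 genes higher and 8 lower, median −0.12 with the test directed up, Benjamini-Hochberg adjusted p = 0.985) or the cell cycle (median −0.09, adjusted p = 0.0594). Against that control Insig1 stood at −0.17, Ccnd1 turned to −0.30, and Cdkn1b was not called (−0.13, adjusted p = 0.259 with edgeR).

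The largest rises by the naming rule included the carbonyl reductase Cbr3 (3.02 ± 0.09), the chemokine gene Ppbp (3.13 ± 0.31, from 0.419 ± 0.0851 to 3.74 ± 0.187 CPM), Sp5 (2.89 ± 0.19), Ltb (2.73 ± 0.23) and Chac1 (2.58 ± 0.24). Against the Virma WT libraries Ppbp turned to −0.66 and Sp5 stood at 0.54. Chac1 and Trib3 (1.64 ± 0.08) belong to the integrated stress and unfolded protein response, of which 8 of 16 members rose and 3 fell (camera, Benjamini-Hochberg adjusted p = 0.00978; adjusted p = 0.18 with an estimated correlation; 8 and 3 adjusted over the list alone). The median of this list was 0.19. With camera and Benjamini-Hochberg adjustment its call was lost without replicate 1 of Mettl3 WT (median 0.18) and without a filter on low counts (0.20, adjusted p = 0.301). It was also lost with the length and GC trend removed, where the median shrank (0.05, adjusted p = 0.0844). Against the Virma WT libraries 10 members were higher and 2 lower, median 0.295 (camera, adjusted p = 0.000221, or 0.177 with an estimated correlation). Sema6d (−2.02 ± 0.18) and Nrk (−1.75 ± 0.09) were among the largest falls.

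Of the m6A writer genes, Wtap rose by 0.60 ± 0.04 and Rbm15 by 0.69 ± 0.06, Mettl14, the partner of Mettl3, fell by 0.78 ± 0.07, and 5 of 8 were not called (camera, Benjamini-Hochberg adjusted p = 0.672). With Virma WT as control, 3 writers were higher and 4 lower, among them Rbm15b (−0.42, edgeR, Benjamini-Hochberg adjusted p = 7.46e-08) and Zc3h13 (−0.13, 0.0237). Rbm15b also passed with the length and GC trend removed (−0.12, adjusted p = 0.0403), and Zc3h13 without replicate 2 of Mettl3 WT (−0.14, 0.00742). Among readers and demethylases 4 of 14 rose and 8 fell (camera adjusted p = 0.854), with Ythdf2 at 0.89 ± 0.04, Ythdc1 at 0.76 ± 0.03, Fmr1 at −0.80 ± 0.05 and Igf2bp3 at −0.65 ± 0.04. The remaining lists were not called by camera, with adjusted p from 0.0534 to 0.96. Their members rose and fell in 3 and 1 of 13 for visceral endoderm, 2 and 6 of 10 for parietal endoderm, 2 and 1 of 12 for the two-cell-like state, 3 and 8 of 17 for trophectoderm, and 4 and 0 of 12 for mesoderm. The counts were 0 and 3 of 9 for neuroectoderm, 3 and 10 of 16 for germline genes, 7 and 3 of 15 for FGF and ERK targets, 7 and 6 of 16 for p53 targets and 2 and 1 of 15 for interferon response genes. Ribosomal protein genes rose in 28 and fell in 35 of 79, histone genes rose in 2 and fell in 7 of 15, and mitochondrially encoded genes rose in 8 and fell in 2 of 13. Adjusted over the list alone, counts were equal except that 2 visceral endoderm and 1 interferon response genes rose, 2 neuroectoderm genes fell, and 29 ribosomal protein genes rose and 38 fell. Camera called the mitochondrial list without replicate 1 of Mettl3 WT (Benjamini-Hochberg adjusted p = 0.0493) or replicate 2 of Mettl3 cKO (adjusted p = 0.00843), and the mesoderm list without replicate 2 of Mettl3 WT (adjusted p = 0.0442) or without a filter on low counts (0.0308). With the length and GC trend removed camera called ribosomal proteins (median −0.15, adjusted p = 1.18e-06), parietal endoderm (−0.32, 0.00546), trophectoderm (−0.35, 0.0243), readers and demethylases (−0.07, 0.0327) and the mitochondrial list (0.50, 0.00318). Against Virma WT it called ribosomal proteins higher (0.12, 0.000106, or adjusted p = 0.347 with an estimated correlation). Mitochondrially encoded genes held 1.7 ± 0.0424% of all counts in Mettl3 WT and 1.64 ± 0.113% in Mettl3 cKO, so their summed share did not rise. Ribosomal protein genes held 7.505 ± 0.0778% and 7.815 ± 0.00707%, so their summed share was higher in Mettl3 cKO. These shares were taken without removing the length and GC trend.

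In total 7835 of 14229 genes tested differed between Mettl3 cKO and Mettl3 WT, 3857 higher and 3978 lower, and 856 of them by at least 2-fold, 624 higher and 232 lower. With all 8 libraries counted separately, as first planned, the count was 8283. Against the Virma WT libraries, with the Mettl3 WT pair left out of the contrast, 8325 genes differed.

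The second comparison sets the libraries labelled Virma cKO against Virma WT. Primitive endoderm genes were much lower: Gata6 fell from 109 ± 2.40 to 12.9 CPM (−3.08 ± 0.09), Gata4 from 215 ± 2.32 to 34.3 CPM (−2.65 ± 0.06) and Sox17 from 37.1 ± 2.68 to 9.93 CPM (−1.91 ± 0.13). Sox7 (−3.41 ± 0.10), Hnf4a (−2.93 ± 0.39), Foxq1 (−2.72 ± 0.08) and Foxa2 (−1.35 ± 0.15) fell too, and Klf6 rose by 0.26 ± 0.05. Effectors fell as well, with Aqp8 at −4.77 ± 0.11, Cubn at −3.92 ± 0.04, Srgn at −3.85 ± 0.09, Lama1 at −3.25 ± 0.03 and Col4a1 at −2.13 ± 0.03. Lama1, an abundant laminin of the basement membrane, went from 2730 ± 17.1 to 288.3 CPM.

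By list, 8 of 9 transcription factors fell and 1 rose, with a median of −2.72 (camera, Benjamini-Hochberg adjusted p = 1.89e-28; adjusted p = 0.0165 with an estimated correlation), and 17 of 19 effectors fell and 0 rose, with a median of −2.01 (camera adjusted p = 1.21e-158; adjusted p = 0.004 with an estimated correlation). Adjusted over the list alone the counts were equal. Fibroblast markers rose in all 13 members tested, median 1.27 (camera adjusted p = 6.92e-16; adjusted p = 0.0468 with an estimated correlation; 13 adjusted over the list alone), and their summed level was 504.2 ± 4.45 CPM in Virma WT and 1212 CPM in Virma cKO. Visceral endoderm genes fell in 8 of 13 and rose in 0, median −1.03, with Dkk1 at −3.77 ± 0.16 and Car4 at −3.34 ± 0.12 (camera adjusted p = 0.00277; adjusted p = 0.0907 with an estimated correlation; adjusted p = 0.125 without a filter on low counts). Parietal endoderm genes rose in 3 and fell in 5 of 10 (camera adjusted p = 0.00148; adjusted p = 0.0907 with an estimated correlation). Their median was −0.17. With camera and Benjamini-Hochberg adjustment the parietal call was lost without replicate 1 or 2 of Mettl3 WT (median −0.17 in each) or replicate 2 of Virma WT (−0.14). It was also lost with the line fitted on its own (median −0.19) or no filter (−0.18, adjusted p = 0.129). The size of the median thus changed little.

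**Figure D2:**
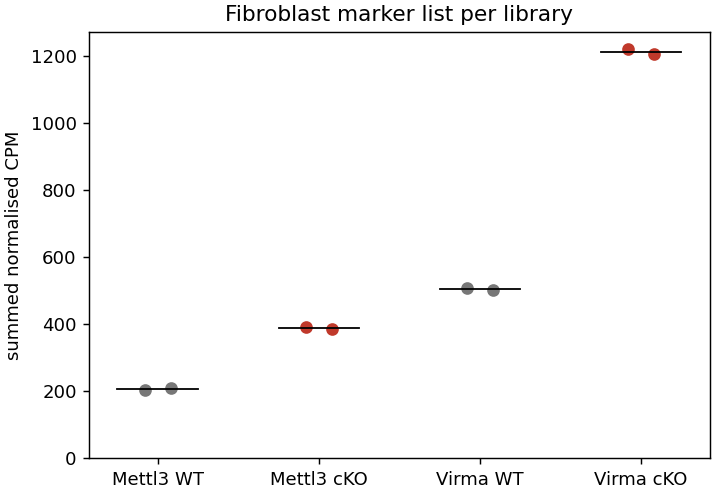
Summed normalised CPM (vertical axis, starting at 0) of the fibroblast marker list in each library of the 4 groups. Points are libraries, grey for WT and red for cKO, and black lines are group means, which were 205.6, 386.6, 504.2 and 1212 CPM from left to right.

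Pluripotency genes were also lower in Virma cKO, where 13 of 20 fell and 4 rose, median −0.51 (camera, Benjamini-Hochberg adjusted p = 1.29e-06; adjusted p = 0.0533 with an estimated correlation; 14 and 4 adjusted over the list alone). Pou5f1 fell by 0.87 ± 0.04, Nanog by 1.19 ± 0.06, Klf5 by 1.20 ± 0.06 and Dppa5a by 1.93 ± 0.04, while Tet2 stood at −0.11 ± 0.06 and was not called. By edgeR with Benjamini-Hochberg adjustment Tet2 passed with the length and GC trend removed (−0.29, adjusted p = 8.74e-05), with the line fitted on its own (−0.13, 0.0321), without replicate 1 of Virma cKO (−0.15, 0.0305), with the replicate block (−0.11, 0.0265) and with 8 separate libraries (−0.11, 0.0313). Of the formative and primed genes 7 of 14 fell and 2 rose (camera adjusted p = 0.00666; adjusted p = 0.111 with an estimated correlation), with Dnmt3b at −1.35 ± 0.04, Dnmt3l at −1.60 ± 0.06 and Sox4 at 0.60 ± 0.05. The median of the formative list was −0.15. With camera and Benjamini-Hochberg adjustment its call was lost without replicate 1 or 2 of Mettl3 WT, where the median was −0.15 in each. It was also lost without replicate 2 of Virma WT (median −0.12) and with the line fitted on its own (−0.17).

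Targets of the tumour suppressor p53 rose in 15 of 16 and fell in 0, median 0.49 (camera, Benjamini-Hochberg adjusted p = 8.90e-08; adjusted p = 0.0468 with an estimated correlation; 15 adjusted over the list alone). Mdm2, the ubiquitin ligase of p53, rose by 0.85 ± 0.03 and Aen by 0.91 ± 0.05. The stress response list rose in 9 and fell in 5 of 16, median 0.28 (camera adjusted p = 0.00354, or 0.0907 with an estimated correlation). Trib3 stood at 2.17 ± 0.08, Chac1 at 2.47 ± 0.26 and Atf5 at 1.49 ± 0.08. The camera call of this list was lost without a filter on low counts (median 0.27, adjusted p = 0.107) and with the line fitted on its own (median 0.26). Glycolysis genes fell in 14 of 16 and rose in 2, median −0.65 (camera adjusted p = 8.34e-21; adjusted p = 0.0468 with an estimated correlation), with Ldha at −1.42 ± 0.04 and the glucose transporter gene Slc2a3 at −1.24 ± 0.03. Cholesterol synthesis genes fell in 14 of 16 and rose in 0, median −0.55 (adjusted p = 1.18e-08; adjusted p = 0.0564 with an estimated correlation). Cell cycle genes fell in 15 of 20 and rose in 2 (adjusted p = 9.55e-06; adjusted p = 0.0597 with an estimated correlation), and ribosomal protein genes fell in 68 of 79 and rose in 3 (adjusted p = 5.65e-17; adjusted p = 0.0564 with an estimated correlation). Counts adjusted over the list alone were equal except for ribosomal proteins, where 69 fell.

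The remaining lists were not called (camera, Benjamini-Hochberg adjusted p from 0.107 to 0.875). Among m6A writers Wtap rose by 0.62 ± 0.05, Rbm15 by 0.96 ± 0.07 and Cbll1 by 0.52 ± 0.11, Rbm15b fell by 0.53 ± 0.06, and Mettl14 stood at −0.05 ± 0.08. With the length and GC trend removed Mettl14 passed the edgeR test (−0.21, Benjamini-Hochberg adjusted p = 0.018; 0.00251 with the replicate block). Zc3h13 was not called (0.11 ± 0.06), but passed with scaling by total count (0.23, adjusted p = 0.00206). It also passed with the replicate block, with 8 separate libraries, and without either Mettl3 WT replicate or replicate 2 of Virma cKO (0.11 to 0.16, adjusted p from 0.0286 to 0.0493). Readers and demethylases rose in 5 and fell in 5 of 14, with Ythdf2 at 1.13 ± 0.05. Other counts of members up and down were 5 and 0 of 12 for the two-cell-like state, 6 and 5 of 17 for trophectoderm, 0 and 3 of 12 for mesoderm, 1 and 2 of 9 for neuroectoderm and 4 and 2 of 16 for germline genes. They were 9 and 5 of 15 for FGF and ERK targets, 7 and 0 of 15 for interferon response genes, 3 and 7 of 13 for imprinted genes, 6 and 1 of 13 for mitochondrially encoded genes and 2 and 0 of 15 for histone genes. Adjusted over the list alone, counts were equal except that 4 genes of the two-cell-like state and 10 FGF and ERK targets rose and 2 mesoderm genes fell. Camera called the mitochondrial list without either Mettl3 cKO replicate (Benjamini-Hochberg adjusted p = 0.0216 and 0.0224) or with the line fitted on its own (0.0242). It called the two-cell-like list without a filter on low counts (adjusted p = 0.033) or with the line on its own (0.0242), interferon response without a filter (0.0487), and readers and demethylases with scaling by total count (0.0175).

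By the naming rule the largest rises included Pde1c (2.89 ± 0.20), Ltb (2.57 ± 0.23) and Cbr3 (2.36 ± 0.09), and the largest falls included Egflam (−4.20 ± 0.20) and Tcf23 (−3.98 ± 0.25). Ffar3 had 88 counts in the Virma WT pair and 2 in the Virma cKO pair, a ratio of 39.7 with an exact 95% interval of 10.7 to 333 that covers counting error only. In total 7439 of 14229 genes differed, 3721 higher and 3718 lower, and 1279 by at least 2-fold, 766 higher and 513 lower. With all 8 libraries counted separately the count was 8914. Scaling by total count moved the median of all genes by 0.127 and the share of higher calls from 50% to 65.4% of 7592.

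The third comparison asks which changes the lines share and where they differ. Ltb, Chac1, Cbr3, Madcam1, Inka1 and Rpl10l had the largest rises common to both, from Rpl10l (1.85 ± 0.08 in Mettl3 cKO, 1.88 ± 0.08 in Virma cKO) to Ltb. Sema6d (−2.02 ± 0.18 and −2.23 ± 0.31), Cacna1d (−1.69 ± 0.19 and −3.46 ± 0.43), Amer1 (−1.47 ± 0.13 and −1.59 ± 0.17) and Tmem186 (−1.41 ± 0.11 and −2.04 ± 0.16) fell in both. The fall of primitive endoderm genes was larger in Virma cKO: the difference of effects was −2.36 ± 0.11 for Gata6, −2.36 ± 0.07 for Gata4, −2.87 ± 0.11 for Sox7, −3.22 ± 0.05 for Cubn and −2.47 ± 0.04 for Lama1. As a list, the transcription factors had a median difference of −2.36 (camera, Benjamini-Hochberg adjusted p = 3.29e-24; adjusted p = 0.0211 with an estimated correlation) and the effectors −1.51 (camera adjusted p = 8.48e-127; adjusted p = 0.00605 with an estimated correlation). For the fibroblast list the difference was 0.31 and was not called (camera adjusted p = 0.082).

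Across genes, 1948 were higher in both lines, where independent lists would share 1008.6 (odds ratio 4.95, 95% interval 4.56 to 5.37, Fisher's exact test), and 2026 were lower in both against 1039.4 (odds ratio 5.25, 4.84 to 5.70). Another 517 were higher in Mettl3 cKO and lower in Virma cKO, and 445 the reverse, against 1007.8 and 1040.3. The WT libraries of the lines are separate, so the comparisons share no control, but they share the estimate of each gene's spread. The intervals of the odds ratios take genes as independent, which they are not, and may be too narrow. Log2 fold changes correlated across genes, which are not independent replicates, with Pearson r = 0.50 and Spearman rho = 0.476. Klf6 (−0.79 ± 0.04 and 0.26 ± 0.05), Sox4 (−0.57 ± 0.04 and 0.60 ± 0.05) and Pou5f1 (0.31 ± 0.03 and −0.87 ± 0.04) went opposite ways, although the rise of Pou5f1 did not pass with the length and GC trend removed (0.04). The effects differed in 5569 genes, higher in Virma cKO in 2552 and lower in 3017, and the share of higher ones was 45.8%, or 60.2% of 5705 with scaling by total count. That scaling also moved the share of higher ones among genes changed in both from 49.0% to 63.0%.

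**Figure D3:**
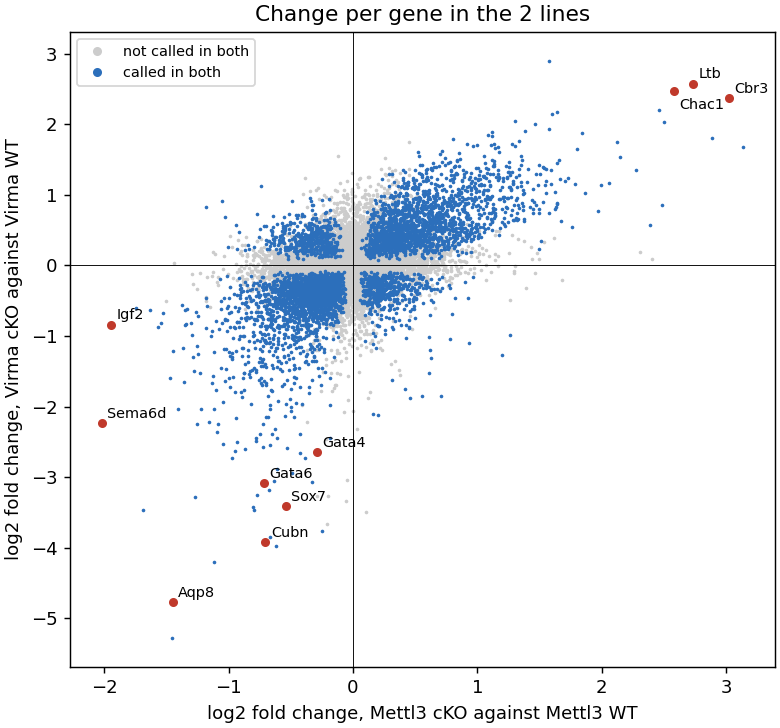
Log2 fold change in Mettl3 cKO (horizontal axis) and in Virma cKO (vertical axis) against the WT libraries of the same line, for genes with an average log2 CPM of at least 2. Blue points passed the test in both comparisons, grey points did not, and named genes are in red. Cubn lies at −0.70 and −3.92, and Cbr3 at 3.02 and 2.36.

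The fourth comparison sets the WT libraries of the lines against each other, Virma WT minus Mettl3 WT, where the line and the library kit cannot be told apart because the labels do not tie kits to libraries. Fibroblast markers were higher in Virma WT in 12 of 13 and lower in 1, median 1.55, with Col3a1 at 1.76 ± 0.06 (camera, Benjamini-Hochberg adjusted p = 1.89e-19; adjusted p = 0.135 with an estimated correlation). Gata6 was lower by a log2 fold change of −0.50 ± 0.05 and Aqp8 by −0.86 ± 0.04, whereas Cubn was higher by 0.41 ± 0.03; of the primitive endoderm effectors 5 of 19 were higher and 11 lower (camera adjusted p = 1.29e-06; adjusted p = 0.136 with an estimated correlation). Formative genes were higher in 10 of 14 and lower in 2, with Dnmt3b at 0.74 ± 0.03 (camera adjusted p = 4.99e-06; adjusted p = 0.135 with an estimated correlation). Cholesterol synthesis genes were lower in 10 of 16 and higher in 1, with Insig1 at −0.58 ± 0.05 (camera adjusted p = 6.51e-09; adjusted p = 0.135 with an estimated correlation). In total 6773 genes differed, 3613 higher and 3160 lower, and 7266 with all 8 libraries counted separately. Camera called 8 of 25 lists, and 0 with an estimated correlation.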

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

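The test of the primitive endoderm genes against the Virma WT libraries was chosen after values of some of these genes had been seen, and the second fibroblast list was fixed after the first list was seen and before its own values were. What singled out the results here, other than the fibroblast list, is a tested difference between the lines. The change in Virma cKO minus the change in Mettl3 cKO passed the edgeR test with Benjamini-Hochberg adjustment in 5569 genes, 39.14% of those tested. It passed in 82 of the 101 named genes, 34 with the higher effect in Virma cKO and 48 with the lower. Many of these were named for large or called effects in the same data, so their share is no separate evidence. For the first fibroblast list the difference was 0.31 and was not called. Camera called 13 lists, or 2 with an estimated correlation. The lines have separate WT libraries, and line and library kit cannot be separated, since the labels do not tie kits to libraries.

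Differences of the effects are given as log2 values, Virma minus Mettl3. Medians of the lists that camera called were −2.36 for primitive endoderm transcription factors, −1.51 for its effectors, −1.14 for visceral endoderm, −1.06 for formative and primed epiblast, −0.79 for mesoderm, −0.32 for pluripotency and 0.41 for p53 targets. They were −0.46 for glycolysis, −0.26 for cholesterol synthesis, −0.24 for the cell cycle, −0.33 for ribosomal proteins, 0.32 for imprinted genes and 0.04 for parietal endoderm, whose mean (−0.24) and test were negative. With an estimated correlation the 2 primitive endoderm lists were called. Among m6A writers the values were Mettl3 −0.38, Virma −0.42, Mettl14 0.73, Rbm15 0.27, Rbm15b −0.45 and Cbll1 0.59. For primitive endoderm transcription factors they were Gata6 −2.36, Gata4 −2.36, Sox17 −1.86, Sox7 −2.87, Hnf4a −2.77, Foxa2 −1.05, Foxq1 −2.33 and Klf6 1.06, and for endoderm effectors and the genes with the largest falls Aqp8 −3.32, Cubn −3.22, Srgn −3.19, Lama1 −2.47, Lamb1 −1.46, Lamc1 −1.16, Col4a1 −1.58, Dkk1 −3.52, Car4 −3.28, Egflam −3.09, Tcf23 −3.36, Tfec −3.45 and Fgf3 −3.59. Pluripotency and epiblast genes had Pou5f1 −1.18, Nanog −0.96, Klf5 −0.36, Dppa5a −1.32, Tfcp2l1 0.44, Tet2 0.74, Dnmt3l −1.14, Dnmt3b −1.02, Utf1 −1.13, Tcf15 −1.14, Dnmt3a −0.30 and Sox4 1.17. Genes of metabolism and the cell cycle had Insig1 −0.32, Cyp51 −0.37, Ldha −0.94, Slc2a3 −0.81, Pfkl −0.88, Pgk1 −0.38, Ccnd1 −0.47, Mcm2 −0.31, Mcm5 −0.59 and Ccnd3 −0.66. Imprinted genes and others that fell more in Mettl3 cKO had Igf2 1.10, Nrk 1.15, Zfp9 1.0, Ndrg1 0.70, Col11a1 0.73, Prkaa2 0.85, Peg10 0.82, Peg3 0.45 and Cdkn1b 0.60. Targets of p53 and stress genes had Trib3 0.54, Atf5 0.66, Psat1 0.31, Mdm2 0.82, Ccng1 0.76 and Trp53inp1 0.71. Other genes with the higher effect in Virma cKO had Pde1c 1.32, Col1a1 0.17, Acta2 0.35, Ythdf2 0.24, Ythdc1 0.13, Fmr1 0.31, Chtf8 2.01, Klhdc7a 1.96, Trim12c 1.86, Pdk4 1.72, Ptprm 1.67 and Cd109 1.63. Other genes with the lower effect there had Ppbp −1.46, Cbr3 −0.66, Sp5 −1.08, Cacna1d −1.77 and Tmem186 −0.63. Ffar3 had −3.82, a fitted value that rests on 2 counts in the Virma cKO pair and is no bound. Differences per gene were not carried through the alternatives. In the knockout comparisons, DESeq2 lost the calls of Chtf8 (0.82), Klhdc7a (0.90) and Pdk4 (0.68) in Virma cKO. That of Trim12c in Mettl3 cKO was lost without replicate 2 of Mettl3 cKO (−0.615).

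Primitive endoderm genes were lower in the libraries labelled Mettl3 cKO, and Mettl3 WT libraries stand apart by their replicate noise and number of genes detected. Against the Virma WT libraries the median of the 28 transcription factors and effectors was −0.334, below 0 by more than the interquartile range over 2 (0.259), against −0.518 with their own control, which argues against the Mettl3 WT libraries as the whole cause. With the length and GC trend removed the median was 1.157 times its earlier value, which argues against that trend. Virma WT is another line, so a difference between lines stays open. The Mettl3 transcript did not pass the test against Mettl3 WT (−0.04 ± 0.07) and was lower against Virma WT (−0.38, edgeR, Benjamini-Hochberg adjusted p = 4.41e-05). This transcript was itself higher in Virma WT than in Mettl3 WT, by 0.34 ± 0.07. Whether the fall of the primitive endoderm genes follows loss of Mettl3 was not tested.

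Fibroblast markers were higher in both knockout comparisons. Of a second list, 90.5% of 21 tested genes were higher in both. Its medians were 0.567 in Mettl3 cKO and 0.956 in Virma cKO, against 1.05 and 1.27 for the first. A larger share of fibroblast RNA may therefore contribute, although the gap in Mettl3 cKO lies close to the limit of 0.5. The second list also did not rise evenly. From Ccn2 to Serpinf1 it ranged from −0.553 to 2.126 in Mettl3 cKO and from 0.055 to 1.743 in Virma cKO. The smaller of the first list's medians was 1.041 after the length and GC trend was removed, which argues against that trend. Col1a1 and Col3a1 reached 413.8 and 226.9 CPM in Virma cKO, and stem cells or endoderm expressing these genes themselves stay open and untested. Against the Virma WT libraries both lists were lower in Mettl3 cKO, at −0.50 and −0.419, so the direction there rests on the control.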

How the results depend on the processing

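Counting the Virma cKO pair as 1 sample, which made the planned fit of 8 separate libraries an alternative, both Virma pairs as 1 sample each, and the Virma WT control were chosen after the data were seen. With both Virma pairs as 1 sample each the counts were 7342 genes for Mettl3 cKO, 5982 for Virma cKO, 4418 for the difference, 4860 between WT libraries and 3332 in both. Under the other filters and scalings, each line on its own, DESeq2 for the knockout comparisons, and an adjusted p of 0.01, the counts of changed genes stayed within 1.5 times the main ones, and no gene called in either knockout comparison was called in the opposite direction except with the length and GC trend removed, where 91 of 7707 were in Mettl3 cKO and 1 of 7327 in Virma cKO, or 112 and 3 with the replicate block. Similar totals did not mean the same genes. With the length and GC trend removed, 5920 of 7707 main calls in Mettl3 cKO and 6821 of 7327 in Virma cKO were kept in direction. DESeq2 kept 5683 of 7835 and 5302 of 7439. A 2-fold minimum, by construction, lowered the counts to 856 for Mettl3 cKO, 1279 for Virma cKO, 660 for the difference, 875 between WT libraries and 326 in both. DESeq2 called 3593 for the difference and 4493 between WT libraries, where the cause was not tested. Camera called 13 lists in Mettl3 cKO with the length and GC trend removed, 13 also with the replicate block, where the cause was not tested. In Mettl3 cKO, Virma cKO, the difference and the WT comparison, an estimated correlation left 0, 5, 2 and 0 lists. That test rests on 3 residual degrees of freedom. Fry, which compares with no other genes, called 20, 20, 18 and 19. Leaving out 1 library at a time gave 6179 to 8208 genes for Mettl3 cKO, 6036 to 8674 for Virma cKO, 4400 to 6655 for the difference, 4923 to 7334 between WT libraries and 3279 to 4417 in both, and 8 to 9, 11 to 14, 11 to 13 and 8 to 9 lists. Deviations of same-numbered replicates correlated at 0.014 in the Mettl3 line and −0.015 in the Virma line. The Virma cKO pair differed by no more than counting noise over all genes, so a low correlation there cannot show whether the numbers pair libraries. In the Mettl3 line no sign of pairing was seen. Counting noise limits that too (chi-square per degree of freedom 1.06 in Mettl3 cKO at a pair sum of 10 to 99). The replicate block, with the Virma cKO libraries counted separately, gave 8189 genes for Mettl3 cKO and 8851 for Virma cKO. It gave 6707 for the difference, 7390 between WT libraries and 4569 in both. Trp53inp1 in Mettl3 cKO turned from −0.13 to 0.18 with the length and GC trend removed, and to 0.18 also with the replicate block; the cause was not tested. With the Virma WT libraries as control, these values of Mettl3 cKO, called under at least 1 of the controls, changed sign, and the cause was not tested: Sox17 0.23, Fgf3 −0.36, Mdm2 −0.076, Mcm5 0.070, Foxa2 0.046, Ffar3 0.76, Ppbp −0.66, mt-Nd3 −4.58, Ccnd1 −0.30, Ccnd3 0.10, Col1a1 −0.39, Col1a2 −0.50, Col3a1 −0.60, Acta2 −0.37, Chtf8 0.23, Klhdc7a 0.46, Trim12c 0.015, the fibroblast list −0.50, the formative list −0.45 and ribosomal proteins 0.12. Camera called 8 lists with that control, and 0 with an estimated correlation. Genes with few counts, such as Ffar3 with 2 in the Virma cKO pair, are limited by depth.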

Other observations

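All tests on long exons were fixed before their results were seen, and the genes mt-Nd3 and Ddx3y were picked out here after their values were seen. The mitochondrial transcript mt-Nd3 stood at 0.15 ± 0.212 CPM in Mettl3 WT (5 counts in the pair) and 0.874 ± 0.209 in Mettl3 cKO (29 counts), but at 21.1 ± 1.06 in Virma WT and 38.3 in Virma cKO. It was called higher in both knockout comparisons (2.49 ± 0.63 and 0.86 ± 0.13; edgeR, Benjamini-Hochberg adjusted p = 0.00185 and 5.53e-06), and against the Virma WT libraries it was lower in Mettl3 cKO by a log2 fold change of −4.58. All 4 tested sex-linked genes were lower in Virma WT than in Mettl3 WT, median −2.65, and Ddx3y, on the Y chromosome, stood at 10.9 ± 1.60, 5.76 ± 0.835, 2.36 ± 0.0431 and 3.06 CPM in Mettl3 WT, Mettl3 cKO, Virma WT and Virma cKO. In Mettl3 cKO 3 of these 4 genes fell, and in Virma cKO 1 rose.

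A hypothesis was tested that genes with an internal exon of at least 500 bases, known as frequent places of m6A, are higher in the libraries labelled cKO. They were compared with genes without one matched on length, GC content and expression (2144 pairs). Their median log2 fold change was higher by 0.084 in Mettl3 cKO (0.02 against −0.064) and by 0.202 in Virma cKO (0.224 against 0.022). The permutation p was 1e-05 in each, the smallest that 100000 permutations can give, and genes are not independent replicates. Both differences had the direction of the hypothesis, which was tested on expression and not on m6A. In Mettl3 cKO, however, the gap lay mostly in the matched genes, which were lower. The same comparison was not made between the WT libraries of the lines. Ratios of the matched to the unmatched difference were 3.205 in Mettl3 cKO, where the unmatched difference was only 0.026, and 0.808 in Virma cKO, which argues against transcript length and GC content as the whole cause.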
